A study of Homo sapiens with 55 samples.

How the data were processed

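The deposited files gave, for each splicing event, the fraction of its isoform listed first among all isoforms of that event in the same sample, from 0 to 1 with 2 decimals. The unit was read from the values and the column names. Per the submitters' processing notes, RSEM 1.2.4, Bowtie, TopHat2 2.0.8b and TopHat were used with the human genome build hg19 (GRCh37). The role of each tool, the step that turned reads into fractions and the rule behind missing values are not given in the sources used here. Per the labels' protocols, libraries were made from polyadenylated RNA with a strand-specific dUTP method and sequenced as paired-end reads. The labels' protocols give a target number of reads per sample but no file gives the reads behind a fraction. The depth is therefore unknown, and no interval or floor that needs it was computed. The files gave no read counts and no gene levels, so the tests of gene levels, of gene lists by level and of the targeted genes' own levels that had been planned were not run. Of the planned tests, those of isoform usage were run, in the form planned for fractions.

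Each of the 4 files had 110818 events, of which 2 had no coordinates and were left out. The 55 listed samples were represented by 54 columns, since the SRSF2 P95H sgGPATCH8 replicate 3 had 1 column for its pair of runs. In the SF3B1 panel each library had a column per sequencing run, and the fractions of its runs were averaged, which left 44 libraries. Whether the runs are repeats of 1 library or separate libraries is not settled: the runs of a library differed by a median of 7.87 points, and different runs of libraries of the same group by 7.87. In the 293T panel the target columns carried guide numbers in place of the labels' group names, and nothing ties a guide to a group name. The 4 columns of a target were used together, with its guides weighted equally, so no result depends on which guide has which group name. The labels give sgRenilla under the name WT-1 only, and each target under WT-1 and WT-2. What these names stand for was not settled. If they are different cells, the WT-2 libraries had no control of their own, and every 293T comparison would be affected.

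In events with an alternative 3' splice site the isoform listed first used the upstream site, which makes the shorter intron. The isoform listed first included the exon in skipped-exon events, used the upstream exon in mutually exclusive exons, was spliced in retained-intron events, used the shorter intron in alternative 5' splice sites and had the shorter 3' UTR in tandem 3' UTR events. For 4 of the 6 types (alternative 3' and 5' splice sites, skipped exons and mutually exclusive exons) the order was compared with the junctions annotated in GENCODE 29. In the SRSF2 panel, alternative 3' splice site events whose isoform listed first was annotated had a median usage of 94.2%, against 16.9% where it was not. The files gave no gene names. GENCODE 29 uses build GRCh38, and no coordinate was converted. Names came from a match of chromosome, strand and exact intron or exon lengths, kept where neighbouring events showed the same shift between the builds, which named 102281 of 110816 events (92.3%), and tandem 3' UTR events stayed almost all without a name.

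For each panel, events with a value in every library were tested where some group mean was at least 5% and some group mean at most 95%. That left 50804 events in the SF3B1 panel, 43933 in the SRSF2 panel, 43415 in the U2AF1 panel and 49019 in the 293T panel. Fractions were turned into the log2 of used over not used, with 0.01 added to each side, and fitted with limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with a mean for each group and a trended prior variance. The groups of a panel shared 1 estimate of the spread, so groups of 1 library were assumed to vary like the others. In the 293T panel each guide had its own mean, so p-values there rest on the spread between replicates of a guide. They leave out differences between guides, which an SD over the 4 libraries of a target includes. In the SF3B1 panel the guides of a target were the libraries of a group, so p-values of these panels differ in meaning. An event was called where the Benjamini-Hochberg adjusted p was under 0.05 and the difference of group means was at least 5 percentage points. With no change in any event, an unadjusted p under 0.05 would be expected for 2540 tested events in the SF3B1 panel. That number is 2197 in the SRSF2, 2171 in the U2AF1 and 2451 in the 293T panel. Differences are given in percentage points, and changes of the log2 ratio with their standard errors (SE). The call rule, the limits on group means, the groups, the comparisons, 20 gene lists and the alternative settings were fixed before the data were examined. The offset of 0.01, the need for a value in every library and the test of gene lists were set once the unit was known. Gene lists were compared with all other genes with a tested event by Fisher's exact test (two-sided), adjusted by Benjamini-Hochberg over the lists. A gene counted as called by any of its events. The test takes no account of how many tested events a gene has, which can raise a list's share. The sources do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. Annotation and figures were made with Python 3.11.15.

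The named genes were the 5 targeted or mutated genes (GPATCH8, SUGP1, SF3B1, SRSF2 and U2AF1) and, for each comparison, those of the 10 largest rises and 10 largest falls among called events (5 for interactions), 1 event per gene, and up to 4 called genes of each fixed list. The other genes named from the SF3B1 target list and the events called in 3 or more panels fall outside this rule and were chosen after their values were seen.

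The test was tried on simulated fractions made from each event's mean over the groups and its spread, with 200 changed events per comparison. The changed events were drawn only from those of intermediate mean usage. There a given number of points is a smaller change of the log2 ratio than at low or high usage. For K700E averaged over guide targets (50804 events), 45.5% of events changed by 30 points were called and 0% of those changed by 10 points. The 1713 real calls of that comparison had a median of 12.2 points in run 1 and 12.5 in run 2. The simulated shares therefore do not carry over to the real events. For every other SF3B1 comparison (50804 events), 0% of events changed by 30 points were called. In the SRSF2 panel (43933 events), 56.1% were called at 30 points for P95H against WT, 28.8% for sgGPATCH8 with WT, 56.1% for sgGPATCH8 with P95H and 27.3% for the interaction. In the U2AF1 panel (43415 events), the shares at 30 points were 27.3% for S34F, 31.8% for sgGPATCH8 with WT, 22.7% for sgGPATCH8 with S34F and 0% for the interaction. In the 293T panel (49019 events) they were 16.7% for sgGPATCH8 and 0% for sgSUGP1. Between 0 and 7 of the unchanged events were called in any comparison, and no changed event was called in the wrong direction. Since these shares do not carry over, how many real changes were missed is unknown. Low counts of calls in the SF3B1 and 293T panels and for the U2AF1 interaction are therefore not read as showing that few events changed.

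Whether replicate numbers pair the libraries was examined from the correlation of same-numbered libraries' deviations from their group means. In the U2AF1 panel it ran from 0.07 to 0.40 over 18 pairs, and all 12 libraries correlated best with a library of their own number. In the comparison of S34F with WT sgRenilla, and in that of sgGPATCH8 with sgRenilla in WT, every pair was over 0.1, so the numbers were taken to pair those libraries. In the other panels no pair exceeded 0.03. Of the SF3B1 libraries 8 of 8 also correlated best with their own number, but with 2 libraries a group their deviations mirror each other and the highest correlation was 0.02. The tally was 4 of 12 in the SRSF2 panel and 6 of 10 in the 293T panel.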

Results

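RNA was sequenced from K562 cells, an established leukemia line, and 293T cells, a line derived from human embryonic kidney. The cells carried guides against GPATCH8 or SUGP1, which encode proteins with a G-patch domain, or a control guide against Renilla luciferase (sgRenilla), a gene that human cells lack. The groups let the loss of these proteins be compared with and without splicing factor mutations found in blood cancers. In K562 these were SF3B1 K700E, knocked in, and SRSF2 P95H and U2AF1 S34F, overexpressed, each beside its wild type (WT). The SF3B1 panel had 10 libraries: 1 per sgRenilla group, and 2 guides for each of GPATCH8 and SUGP1 in WT and in K700E cells. The SRSF2 and U2AF1 panels had 12 libraries each, 3 per group. The 293T panel had 2 sgRenilla libraries, both labelled WT-1, and, for each target, 2 guides with 2 replicates each, labelled WT-1 and WT-2. Its p-values do not cover differences between guides. The measurement was the usage of the isoform listed first in each splicing event, in percent. The columns gave a value for 72.4% to 78.1% of events in the SF3B1 panel, 73.6% to 77.5% in the SRSF2 panel, 73% to 74% in the U2AF1 panel and 77.6% to 78.4% in the 293T panel. The depth behind the values is unknown.

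The targeted genes could be followed only through their own splicing, which does not show whether a guide removed its protein. Loss of a gene, and cells without it, stand below for libraries with a guide against it. None of the tested events of GPATCH8 passed the test (limma) for sgGPATCH8 in the SF3B1, U2AF1 or 293T panels or in WT SRSF2 cells, and none of SUGP1 passed for sgSUGP1. In SRSF2 P95H cells 2 of 3 GPATCH8 events were called for sgGPATCH8, in a comparison with 2128 calls. Of genes that this guide does not target, 1 of 2 SF3B1 and 1 of 4 U2AF1 events were called there too. For SUGP1 it was 0 of 9 and for SRSF2 0 of 4. The GPATCH8 calls are therefore no sign of the guide's action on its target. Inclusion of a GPATCH8 exon on chromosome 17 fell from 97% ± 2 (SD, n = 3) to 82.3% ± 4.5 (n = 3; limma adjusted p 0.02).

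SF3B1 helps the U2 snRNP find the branch point, and K700E is its most common mutation in myelodysplastic syndromes. Known K700E targets moved strongly. TMEM14C, which carries a heme precursor into mitochondria, used an upstream 3' splice site 14 nt from the usual one (chromosome 6, 10723474 to 10724789) in 58.5% of transcripts with K700E and 5% with WT in the sgRenilla libraries. PPOX, a heme synthesis enzyme, used its upstream site in 88% and 41%. MAP3K7, a kinase of NF-kappaB signalling, did so in 63% and 9.5%, and the calcium channel gene ORAI2 in 72.5% and 9%. In BRD9, a chromatin remodelling gene, inclusion of a poison exon was 51.5% with K700E and 7% with WT. Usage of the upstream site in MTERF2 was 5% with K700E and 67.5% with WT, and in the long noncoding RNA CRNDE 14.5% and 74.5%. Each of these values is 1 library.

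With 1 sgRenilla library per genotype, limma called 0 of 50804 events between them, while 6578 had an unadjusted p under 0.05 and the lowest adjusted p was 0.081. The 0 depends on the setting: 22 were called with an offset of 0.05, 21 in run 2 alone and 844 with both runs as columns, a setting whose counts are liberal here and below. Averaged over the guide targets (5 libraries of each genotype), 1713 events in 1081 named genes were called, of which 1091 rose and 622 fell. In run 1 alone 117 events were called, in run 2 alone 277 and with both runs as columns 3907. The 8 libraries with a guide against GPATCH8 or SUGP1, left out singly, gave 213 to 474 calls, the lowest without the K700E sgSUGP1 replicate 1. TMEM14C rose by 40.5 points (log2 ratio 3.25 ± 0.21 SE, limma adjusted p 0.0071), ORAI2 by 46.7 points (3.53 ± 0.23, limma adjusted p 0.0071) and BRD9 exon inclusion by 33.2 points (2.50 ± 0.22, limma adjusted p 0.011). MAP3K7 rose by 29.7 points, DPH5 by 29.7, DYNLL1 by 28.3, COASY by 21 and ZDHHC16 by 17.6. These averages join guide targets that could differ, as the sgSUGP1 and sgGPATCH8 values of MAP3K7 below show. MTERF2 fell by 47.4 points (log2 ratio −3.97 ± 0.17 SE, limma adjusted p 0.0071), CRNDE by 39.2, SLC3A2 by 31.5 and DVL2 by 19.8. Of the list of SF3B1 targets fixed beforehand, 27 genes had a tested event and 20 a called one, 16 with a rise and 10 with a fall, against 1061 of 10686 other genes (odds ratio 25.9, two-sided Fisher's exact p 4.5e-15, Benjamini-Hochberg adjusted 8.5e-14). Adjusted over the list alone, 64 of its 191 events passed in the averaged comparison and 45 in the sgRenilla libraries.

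**Figure D1:**
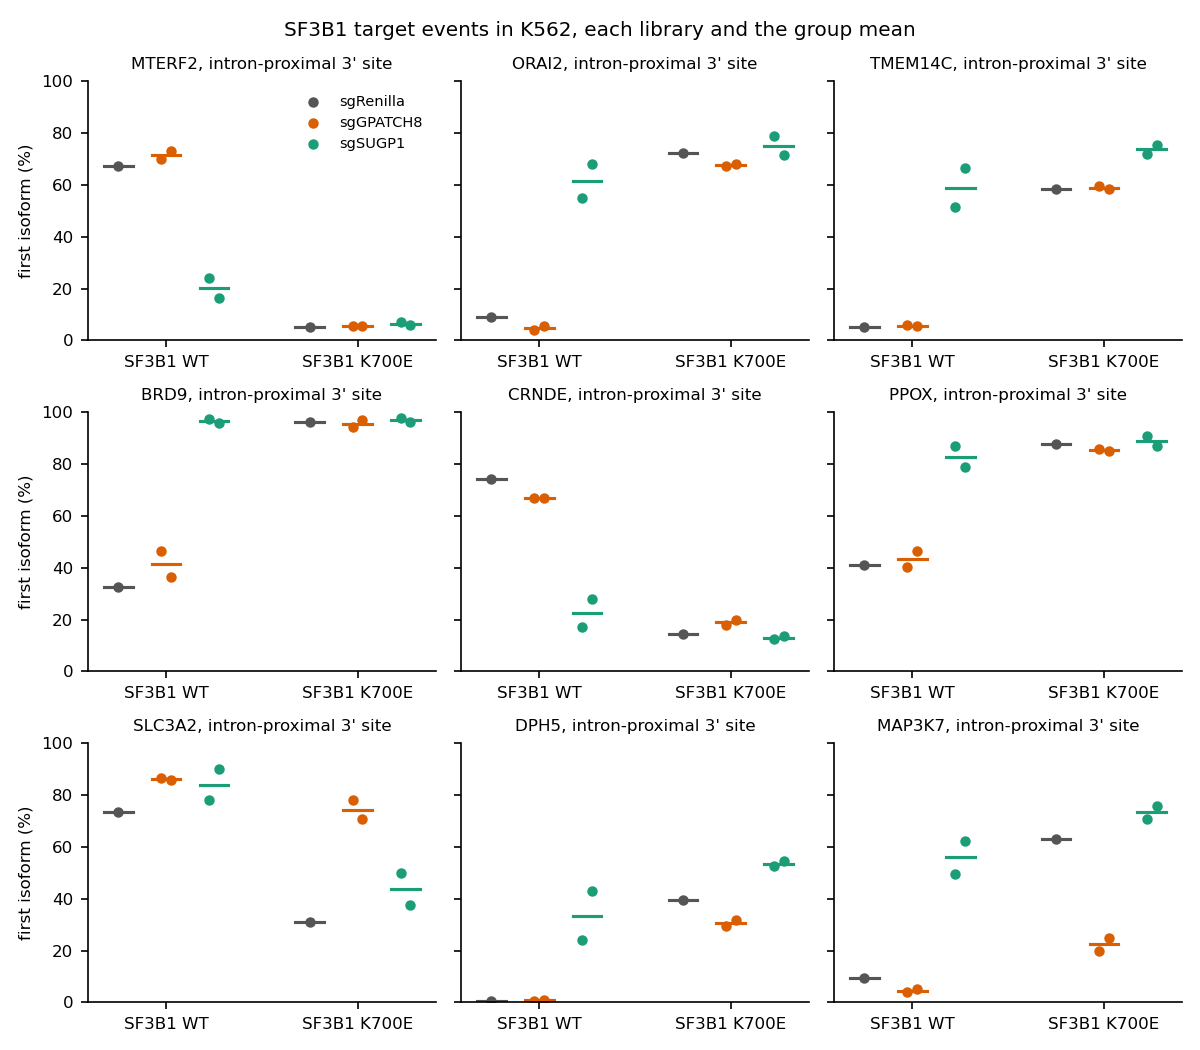
Usage in percent of the isoform listed first (vertical axis) in each library of the SF3B1 panel for 9 genes of the SF3B1 target list, by genotype and guide target. Each point is a library, the mean of its sequencing runs, and bars are group means.

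Genes of heme biosynthesis and mitochondrial iron were called more often than others with K700E, 7 of 14 against 10% of other genes (odds ratio 8.96, two-sided Fisher's exact p 0.00019, Benjamini-Hochberg adjusted 0.0018). These 14 genes had 92 tested events, a number the test does not allow for. Besides TMEM14C and PPOX, an exon of ALAS2, the erythroid enzyme that starts heme synthesis, rose by 12.2 points, while exons of ALAD and the heme exporter FLVCR1 fell by 14.6 and 13.5 points. The largest rises outside the list were exons of the lipid phosphatase PLPP1 (61.3 points, log2 ratio 4.34 ± 0.40 SE, limma adjusted p 0.011), CCDC173 (52.8), ENTPD1 (46.9) and ATXN1 (42.3), and an upstream 3' splice site, 17 nt away, in the nuclease gene GEN1 (54 points). The mitotic checkpoint kinase gene BUB1B rose by 17.7 points at a site 15 nt upstream. Exons of AHNAK and TUBB2B fell by 41.2 and 41 points. In SUGP1 itself usage of an upstream 3' splice site fell by 5.9 points (limma adjusted p 0.019), and in SF3B1 it rose by 21.1 points (limma adjusted p 0.049). By type, 455 called events were alternative 3' splice sites (295 rose, 160 fell), 802 were skipped exons (594 rose), 143 were alternative 5' splice sites, 132 retained introns and 86 tandem 3' UTRs (76 fell). Among alternative 3' splice sites with a pair of sites, those 10 to 30 nt apart, a window chosen after the values were seen, rose in 73 of 1281 tested events, against 184 of 10577 at other distances (5.7% against 1.74%, two-sided Fisher's exact p 2.6e-15).

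SUGP1 binds SF3B1, and K700E weakens that contact. In WT K562 cells without SUGP1, COASY, the gene of the last enzyme of coenzyme A synthesis, included an exon in 46.2% ± 1.1 (SD, n = 2) of transcripts against 9% in the sgRenilla library (limma adjusted p 0.048). In the T-cell adaptor gene SH2D2A an upstream 3' splice site rose to 47.8% ± 6 (n = 2) from 5%, and in MINDY4 to 39.5% ± 1.4 from 5.5%. Exons of ABCC5, TMEM214 and NPIPB5 rose by 39.8, 33.2 and 22.2 points. Usage fell from 85.5% to 20.5% ± 2.8 in ENOX2, from 94% to 38% in ST5, from 96.5% to 57.5% in RBM18 and from 95.5% to 61.3% in DVL2. These 10 events (6 rose, 4 fell) were all that limma called in WT cells, and 4381 had an unadjusted p under 0.05. No event was called in run 1 alone or in run 2 alone, without the sgSUGP1 replicate 1 or 2, or with a missing value allowed (0 calls each), and 358 were with both runs as columns. All 10 went the same way in run 1, by a median of 35.2 points, and the 9 with a value in run 2 by 40 points. COASY and DVL2 belong to the SF3B1 target list (2 of 27 genes, two-sided Fisher's exact p 0.00027, Benjamini-Hochberg adjusted 0.0051). Adjusted over the list alone, 46 of 191 events in 21 genes passed. Among them BRD9 exon inclusion was 64.8% in WT sgSUGP1 cells (n = 2), against 7% in the WT and 51.5% in the K700E sgRenilla library, TMEM14C was 59%, PPOX 83% and MAP3K7 56%.

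In 293T cells without SUGP1 (n = 4 against 2) limma called 21 events in 19 genes, 18 up and 3 down. TMEM14C rose from 7.5% ± 0.7 (SD, n = 2) to 47.8% ± 9 (n = 4; limma adjusted p 0.023), the dynein light chain gene DYNLL1 from 8.5% ± 0.7 to 44.2% ± 3.8, MAP3K7 from 3.5% ± 2.1 to 35% ± 3.8, the BRD9 exon from 4.5% ± 0.7 to 36.2% ± 8.2 and COASY from 8% to 36.8% ± 4.5. GUSBP11, ZNF771, MINDY4, MIPOL1 and SKIV2L rose by 27.5 to 34.5 points. ENOX2 fell from 83% ± 1.4 to 33.8% ± 5.3, CRNDE from 92% to 45.2% ± 5 and BCAM from 98.5% ± 0.7 to 78.2% ± 4.3. Of the SF3B1 target list 6 of 27 genes were called (odds ratio 235.96, two-sided Fisher's exact p 3.3e-12, Benjamini-Hochberg adjusted 6.3e-11), and 28 of its 188 events adjusted over the list alone. Among alternative 3' splice sites with a pair of sites, 11 of 1205 events 10 to 30 nt apart rose, against 1 of 9867 at other distances (two-sided Fisher's exact p 2.6e-10). All 21 calls had the same sign as the K700E effect averaged in K562, and 20 of 21 as SUGP1 loss in WT K562 cells. The 293T libraries enter neither K562 comparison, and those share libraries with each other, so the counts of 21 and 20 are not independent. Across all events the correlations of the log2 effects were low, 0.073 with K700E and 0.128 with SUGP1 loss in K562, and events are not independent replicates. Leaving out any of the 4 sgSUGP1 or 2 sgRenilla libraries left 0 calls. Guide 3 alone gave 2 calls and guide 4 alone 8, an offset of 0.05 gave 39 and a missing value allowed 11.

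With K700E, the loss of SUGP1 gave 48 calls, 5 up and 43 down. They included the DNA repair gene OGG1 (52.3 points up), the ferritin gene FTH1 (100% against 70%), KRT10 (46.7 points down), PRPF38B, a splicing factor gene (44.2 points down), HMG20B, SIRT7 and RAP1B, and 29 were tandem 3' UTR events. Without tandem 3' UTR events 4 were called. No event was called in run 1 alone and 1121 in run 2 alone, and 28 of the 48 went the same way in run 1, where their median difference was 0.5 points against 50 in run 2. HMG20B, SIRT7 and RAP1B fell by 44, 36.8 and 36 points over both runs, while in run 1 their differences were 0.5, 3 and 5 points in the other direction. Each K700E sgSUGP1 replicate left out gave 0 calls, an offset of 0.05 gave 73, a missing value allowed 29 and both runs as columns 31. For the interaction of K700E and SUGP1 loss limma called 0 events, with 4711 at an unadjusted p under 0.05, and 53 in run 2 alone and 50 with both runs as columns. Adjusted over the SF3B1 list alone, 23 of its events in 14 genes passed.

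Several known K700E targets had similar values with and without GPATCH8. TMEM14C used the upstream site in 59% of transcripts in K700E cells with sgGPATCH8 (n = 2) and 58.5% with sgRenilla, BRD9 included its exon in 59% and 51.5%, PPOX used the upstream site in 85.5% and 88%, ORAI2 in 67.8% and 72.5%, and DYNLL1 in 48.2% and 48.5%. Others lay closer to WT. MAP3K7 was at 22.5% in the K700E sgGPATCH8 libraries (20% and 25%) against 63% in the sgRenilla library, ZDHHC16 at 23.8% against 38.5% and DPH5 at 30.8% against 39.5%. SLC3A2 was at 74.5% against 31%, with 73.5% in the WT sgRenilla library. None passed the test of the interaction of K700E and GPATCH8 loss (limma adjusted p 0.46 for MAP3K7, 0.61 for ZDHHC16 and 0.65 for SLC3A2), and adjusted over the SF3B1 list alone 0 of 191 events passed. MAP3K7, ZDHHC16, DPH5 and SLC3A2 were singled out after their values were seen.

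The K700E effect, as the median over 100 events picked in the sgSUGP1 libraries, was 2.8 points with sgRenilla and 5.2 with sgGPATCH8. Of these events 18 were tandem 3' UTR events. The WT sgSUGP1 libraries already used sites such as that of TMEM14C about as much as K700E cells, so these picks can miss known targets. The difference of 2.5 points turned sign with other events. On the 1713 events of the averaged comparison it was −1.7 points and on all 191 tested events of the SF3B1 list −1.2. On the 47 list events called in the averaged comparison the effect was 26 points with sgRenilla and 23 with sgGPATCH8. The difference there was −3 (−4 with each guide). On the 21 events called for SUGP1 loss in 293T the difference was −3 (−4 with guide 16 and −1.5 with guide 17). In run 2 alone the 441 events picked gave 2.5 points, and in run 1 no event was picked. The 1713 events, with the 47 among them, were picked on libraries that include those compared, which limits their values of −1.7 and −3. Of the 21 events, picked in other cells, 14 had a smaller effect with sgGPATCH8. Each of these medians describes 1 sgRenilla library per genotype.

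**Figure D2:**
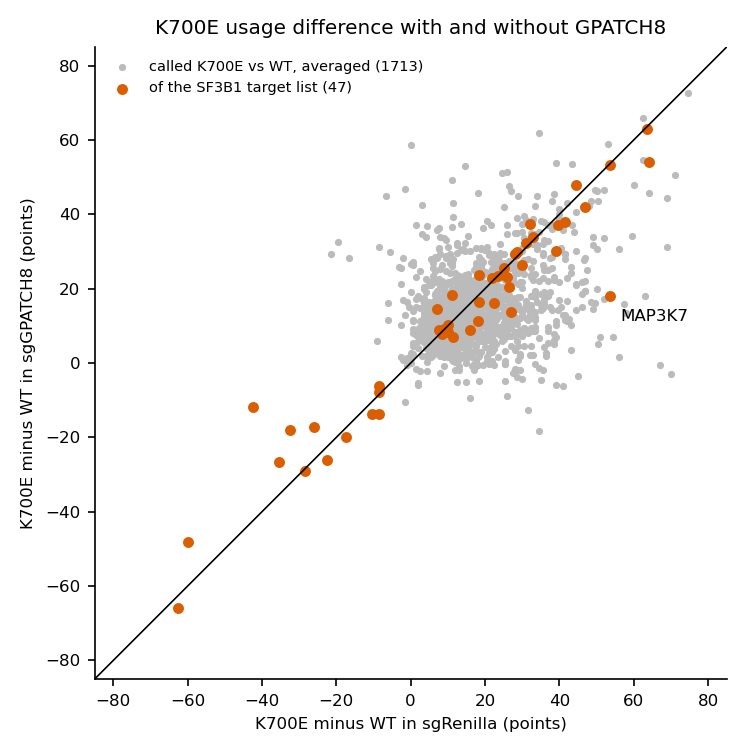
K700E effect (percentage points of usage, K700E minus WT) in the sgGPATCH8 libraries (vertical axis) against the sgRenilla libraries (horizontal axis). Each point is an event. Grey points are events called in the averaged comparison, signed so that the effect in that comparison is positive. Orange points are those of the SF3B1 target list, shown as K700E minus WT without that sign.

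Loss of GPATCH8 in the SF3B1 panel changed DDX11, which encodes a helicase of sister chromatid cohesion. The intron on chromosome 12 from 31242424 to 31242774 was spliced in 4.2% ± 0.4 (SD, n = 2) of transcripts in WT sgGPATCH8 cells and 54% with sgRenilla (limma adjusted p 0.033), and in 6.5% ± 0.7 (n = 2) and 58.5% with K700E. An alternative 5' splice site of the ciliary dynein gene WDR60 rose to 49.2% ± 4.6 (n = 2) from 5% with K700E. These were 3 calls in WT (1 up, 2 down, both in DDX11) and 7 in K700E (1 up, 6 down), with 4805 and 5328 events at an unadjusted p under 0.05. The other 5 were tandem 3' UTR events. Run 1 alone gave 0 calls in each, and run 2 alone 6 in WT and 36 in K700E. Each sgGPATCH8 replicate left out gave 0 calls in its genotype, both runs as columns gave 286 and 355, and an offset of 0.05 gave 30 in K700E. The interaction of K700E and GPATCH8 loss had 15 calls, 14 of them tandem 3' UTR events that fell, and an exon of DNAJC2 that rose. It had 0 calls without tandem 3' UTR events, 0 in run 1 alone, 310 in run 2 alone, 7 with both runs as columns, 39 with an offset of 0.05 and 0 without any of the 4 sgGPATCH8 libraries.

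SRSF2 is an exon-binding SR protein, and P95H changes the motifs it prefers. In K562 cells with P95H, exon inclusion rose from 18% ± 1 (SD, n = 3) to 44.3% ± 1.5 (n = 3) in NBEAL2, a platelet granule gene (limma adjusted p 0.0012), from 27.3% ± 4.6 to 52.7% ± 1.5 in the adhesion receptor gene CD44, from 29.3% ± 7.5 to 58.7% ± 1.5 in the integrin gene ITGB4 and from 59.7% ± 4.6 to 82% ± 2 in the kinase gene FYN. Inclusion fell from 83% ± 4.6 to 41.7% ± 6.7 in the kinase gene FES, and usage of an upstream 3' splice site fell from 57.7% ± 10.7 to 20% ± 1.7 in IRF7, an interferon regulator. SRSF2 itself spliced the intron on chromosome 17 from 74730644 to 74731143 less, 29.3% ± 1.2 against 50.3% ± 1.2 (limma adjusted p 0.0055). A GPATCH8 exon rose from 86.3% ± 1.2 to 96% ± 1, and HNRNPA1 fell from 83% to 66% and HNRNPD from 14.7% to 4.7% at alternative 5' splice sites. Limma called 475 events in 363 genes, 212 up and 263 down. Retained introns were spliced more in 53 of 58 called events, the upstream site was used less in 56 of 63 alternative 3' splice sites, and the shorter intron less in 33 of 40 alternative 5' splice sites. Of the fixed SRSF2 list FYN, INTS3 and GNAS rose (3 of 13 genes, two-sided Fisher's exact p 0.01, Benjamini-Hochberg adjusted 0.082), and 9 events in 7 genes passed adjusted over the list alone. The U2AF1 list had nearly the same values, 3 of 14 genes (p 0.013, adjusted 0.082) and 7 events in 4 genes adjusted over the list alone, so this is not specific to the SRSF2 list. Each of the 6 libraries left out gave 79 to 111 calls, 79 without the P95H sgRenilla replicate 3.

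GPATCH8 loss in WT SRSF2 cells lowered inclusion of an exon of DST, a cytoskeletal linker gene, from 78.7% ± 3.2 (SD, n = 3) to 22% ± 5.3 (n = 3; limma adjusted p 0.00078), of ACOT9, a mitochondrial thioesterase gene, from 72.7% ± 2.1 to 23.3% ± 3.1, and of UGGT1, a glycoprotein folding sensor gene, from 75.3% ± 2.1 to 29.7% ± 7.2. A DDX11 intron was spliced in 13.7% ± 3.5 against 54% ± 6.1. ADGRG6, BAZ2B and AMY2B exons fell by 49.3, 48.7 and 47.3 points. Usage rose in the deacetylase gene SIRT2 from 27.7% ± 7.6 to 72.3% ± 5.8, in WDR60 from 32% ± 1 to 72.3% ± 2.5, in ACSL6 by 36.3 points and in ACIN1, a gene of an exon junction factor, from 18.3% ± 1.5 to 49.7% ± 2.1. Limma called 216 events in 171 genes, 91 up and 125 down, of which 127 were skipped exons (55 up, 72 down). Of alternative 3' splice sites with a pair of sites 10 to 30 nt apart, 8 of 1011 fell, against 12 of 8716 at other distances (two-sided Fisher's exact p 0.00053). For rises it was 4 against 7 (Fisher's exact p 0.021). With P95H neither falls nor rises differed (Fisher's exact p 0.69 and 0.78). The U2AF1 target list was called more often than other genes (H2AFY, IRAK4 and PICALM, 3 of 14, two-sided Fisher's exact p 0.0015, Benjamini-Hochberg adjusted 0.028). Each of the 6 libraries left out gave 104 to 120 calls, 104 without the WT sgGPATCH8 replicate 1.

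In P95H cells GPATCH8 loss moved many of the same exons: UGGT1 fell from 88% ± 1 (SD, n = 3) to 23% ± 1.7 (n = 3; limma adjusted p 3.1e-05), ACOT9 from 72.3% ± 1.5 to 18.7% ± 1.2 and DST by 53.3 points, and SIRT2 rose from 34% ± 7 to 83% ± 5.2. PSPH, a serine synthesis gene, rose from 30.7% ± 7.6 to 91% ± 1.7 and TRAK2, a mitochondrial transport gene, from 35.3% ± 1.5 to 83.3% ± 3.8. EPB41L2 fell by 63.7 points, ADGRG6 by 62.3 and LMO7 by 53.3. Limma called 2128 events in 1417 genes, 830 up and 1298 down, of which 1165 were skipped exons (386 up, 779 down) and 239 retained introns (180 spliced less). The calls shared 147 events in the same direction with WT cells, where independent lists would share 5.41, and the groups share no library. All 3 target lists had higher shares of called genes than the 14% of other genes: 10 of 27 for SF3B1 (37%, Benjamini-Hochberg adjusted Fisher's exact p 0.048), 5 of 13 for SRSF2 (38.5%, adjusted 0.17) and 6 of 14 for U2AF1 (42.9%, adjusted 0.08). So did most other lists, such as myeloid markers (42.9%) and cell cycle (33.3%), while p53 targets had 0%. The target lists had 172, 97 and 86 tested events. A gene with more events has more chances of a call, which the test ignores. Each of the 6 libraries left out gave 1107 to 1310 calls, 1107 without the P95H sgRenilla replicate 3, and a minimum of 10 points left 1413. The interaction of P95H and GPATCH8 loss had 27 calls in 22 genes, 9 up and 18 down, led by PSPH (54.3 points), COL7A1 (53.7) and RABL2A (−43.7), and each of the 12 libraries left out gave 5 to 12. It had 55 calls with an offset of 0.05 and 15 with a missing value allowed, where RABL2A lost its call. Most of the P95H calls went the way of a difference that separates other libraries. In the U2AF1 panel the 4 libraries numbered 1 differ from those numbered 2 and 3 in every group, and of 2039 P95H calls that differ there 1832 (89.8%) had the same sign, against 140 of 210 calls (66.7%) with WT SRSF2 and 24 of 25 interaction calls. Among the U2AF1 libraries numbered 2 and 3, PSPH was at 54% to 71% with sgGPATCH8 and 28% to 44% with sgRenilla, and TRAK2 at 51% to 75% and 34% to 45%. These comparisons were chosen after the values were seen.

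U2AF1 recognises the 3' splice site, and S34F alters its preference for the neighbouring base. Limma called 1 event between S34F and WT, with 4051 at an unadjusted p under 0.05: CTNNB1, which encodes beta-catenin, used an upstream 3' splice site (chromosome 3, 41280845 to 41281151) in 83.3% ± 2.1 (SD, n = 3) of transcripts against 49.3% ± 0.6 (n = 3; limma adjusted p 0.023). With the replicate number as a block 15 events were called. CTNNB1 lost its call without any of the 6 libraries. No event was called (0) without the WT sgRenilla replicate 1 or 2 or the S34F sgRenilla replicate 1, 2 or 3, and 1 other event was called without the WT sgRenilla replicate 3. Without the 4 libraries numbered 1, limma called 0 events, with 5178 at an unadjusted p under 0.05. Of the fixed U2AF1 list 0 of 14 genes had a called event, and 12 of its 91 events in 8 genes passed adjusted over the list alone, as did 7 of 92 events in 3 genes of the SRSF2 list.

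GPATCH8 loss in WT U2AF1 cells gave 14 calls, 2 up and 12 down. ACOT9 fell from 74.3% ± 4.2 (SD, n = 3) to 25% ± 2.6 (n = 3; limma adjusted p 0.0047), splicing of a DDX11 intron from 54.3% ± 4 to 16.7% ± 3.1 and ACTN4, an actin crosslinker gene, from 81.3% ± 0.6 to 54.7% ± 2.5. ADGRV1, CLASP2, KIF13A, KANSL3 and PICALM fell by 16.3 to 45.3 points, and ACIN1 and the kinase gene CSNK1D rose by 26.7 and 11.7 points. With the replicate number as a block 25 events were called, and 5 to 12 with a library left out (5 without WT sgRenilla replicate 2 or WT sgGPATCH8 replicate 3, 6 without WT sgGPATCH8 replicate 2, 8 without WT sgRenilla replicate 3). With S34F there were 15 calls, 4 up and 11 down, 12 of them shared with WT. ACIN1 rose from 23.7% ± 2.9 to 56% ± 1, PIP5K1C by 31.7 points and a DDX11 3' splice site by 37 points, while ACOT9 fell from 58.7% ± 1.5 to 10.3% ± 3.5. Left out singly, the S34F sgRenilla replicates 2 and 3 gave 5 and 4 calls and the S34F sgGPATCH8 replicates 1 and 3 gave 9 and 4. Without the 4 libraries numbered 1, GPATCH8 loss gave 0 calls by limma with WT and 0 with S34F, and 3267 and 5154 events had an unadjusted p under 0.05. Limma called 0 events for the interaction of S34F and GPATCH8 loss, with a lowest adjusted p of 0.59. An unadjusted p under 0.05 was found for 1910 events, fewer than the 2171 expected with no change.

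In 293T cells without GPATCH8 (n = 4 against 2) the DST exon fell from 88% ± 2.8 (SD, n = 2) to 32% ± 12.9 (n = 4; limma adjusted p 0.017), ACOT9 from 66.5% ± 2.1 to 19.2% ± 5.7, the axon guidance gene SLIT2 from 76% ± 4.2 to 23% ± 7.7, EPB41 from 78% ± 1.4 to 31% ± 5.4 and ACTN4 from 93.5% ± 0.7 to 55.2% ± 3.3. RALGAPA1, MARK3, CLASP1 and DDX11 fell by 39.3 to 44.8 points. ACSL6 rose from 12.5% ± 0.7 to 58.5% ± 7.3, SIRT2 from 20% ± 2.8 to 53.5% ± 2.9, WDR60 from 7% to 39.2% ± 4.3 and ALDOC from 8.5% ± 0.7 to 39% ± 3.7. Limma called 33 events in 26 genes, 7 up and 26 down. Of these, 22 were skipped exons (5 up, 17 down) and 5 were introns spliced less. H2AFY and PICALM of the U2AF1 list were called (2 of 14, two-sided Fisher's exact p 0.00049, Benjamini-Hochberg adjusted 0.0093). Leaving out any of the 4 sgGPATCH8 or 2 sgRenilla libraries left 0 calls, guide 16 alone gave 0 and guide 17 alone 14, and 15 were called with a missing value allowed.

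Across the panels, GPATCH8 loss changed a small set of events alike. The 2 DDX11 intron events were called in all 4 panels and fell in each. Another 7 events in 6 genes were called in 3 panels: KANSL3, ACTN4, PICALM, ACOT9 and a pair in DDX11 fell and WDR60 rose. A further 22 events in 19 genes were called in 2 panels (15 fell, 7 rose), such as ACIN1, SIRT2, DST, CLASP2 and ACSL6. No event called in 2 or more panels changed direction between them. ACOT9 fell by 49.3 points in WT SRSF2 cells, 49.3 in WT U2AF1 cells and 47.2 in 293T cells, and was 50.5 points lower in WT SF3B1 cells, where it did not pass (limma adjusted p 0.24). Of the 216 calls in WT SRSF2 cells 23 were also called in 293T cells, all in the same direction, where independent lists would share 0.09. With WT U2AF1 cells 11 were shared against 0.04. Of the 29 293T calls tested in WT SF3B1 cells 28 had the same sign there. Over all events the log2 effects in 293T correlated weakly with those in K562, from 0.063 in K700E SF3B1 cells to 0.155 in WT SF3B1 cells, and those of WT and K700E SF3B1 cells correlated at −0.032. The U2AF1 list passed the adjusted test in WT SRSF2 and 293T cells, but not in U2AF1 cells. In WT U2AF1 cells 1 of 14 genes was called, 7.1% against 0.1% of other genes (two-sided Fisher's exact p 0.016, Benjamini-Hochberg adjusted 0.28). In S34F cells it was also 1 of 14, 7.1% against 0.1% (Fisher's exact p 0.014, adjusted 0.26). In WT and in K700E SF3B1 cells 0 of 14 were called, but hardly any other gene was, so this cannot show an absence. No test compared the panels. Adjusted over the list alone, 2, 2, 6 and 7 of the list's events passed in WT U2AF1, S34F U2AF1, WT SF3B1 and K700E SF3B1 cells.

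**Figure D3:**
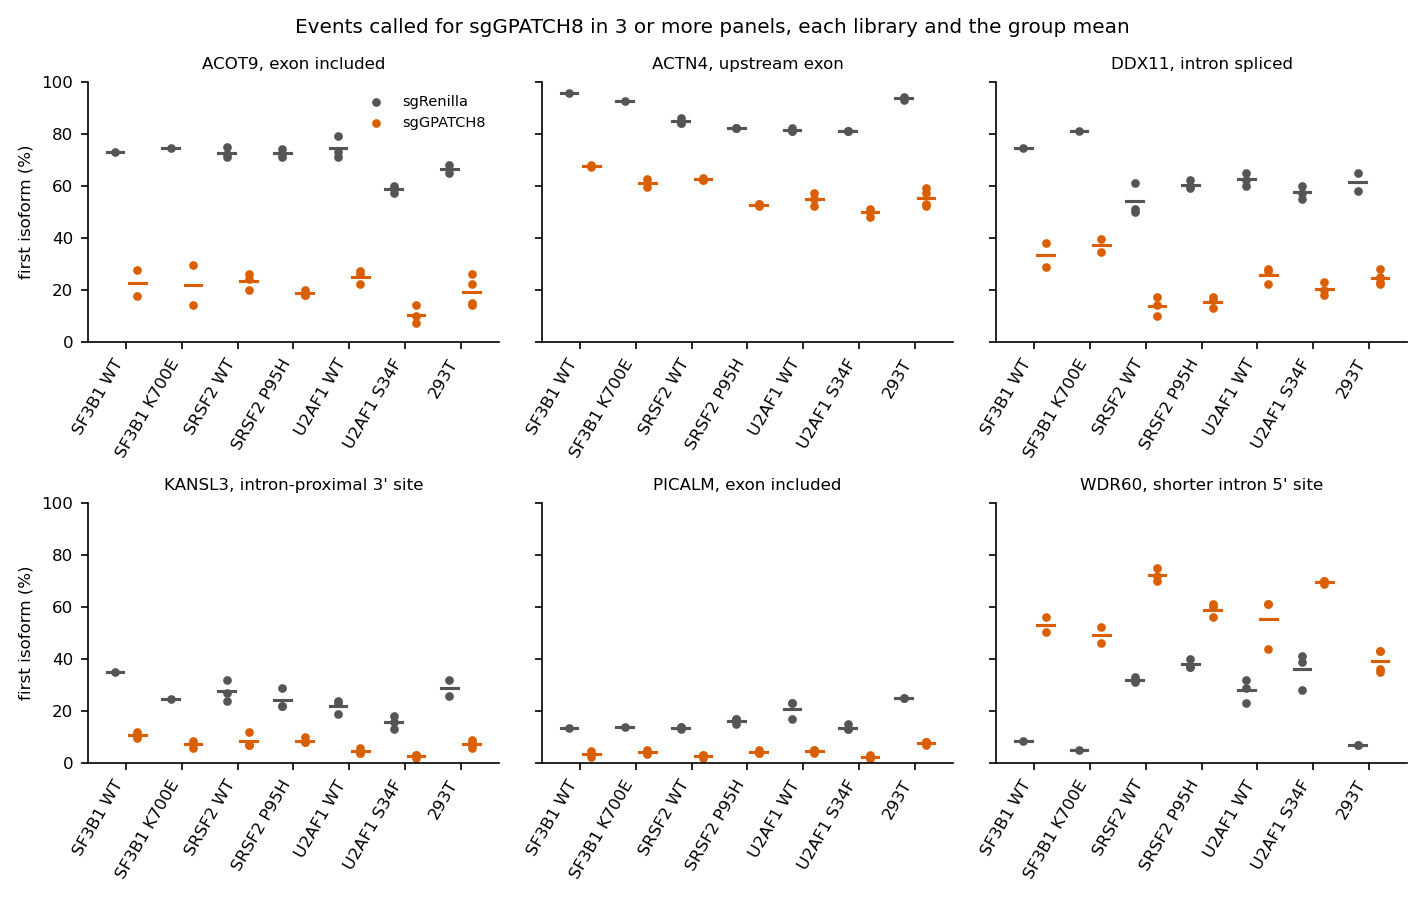
Usage in percent of the isoform listed first (vertical axis) in each library of the 4 panels for the 6 genes with an event called for GPATCH8 loss in 3 or more panels, 1 event per gene. Each point is a library and bars are group means.

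**Figure D4:**
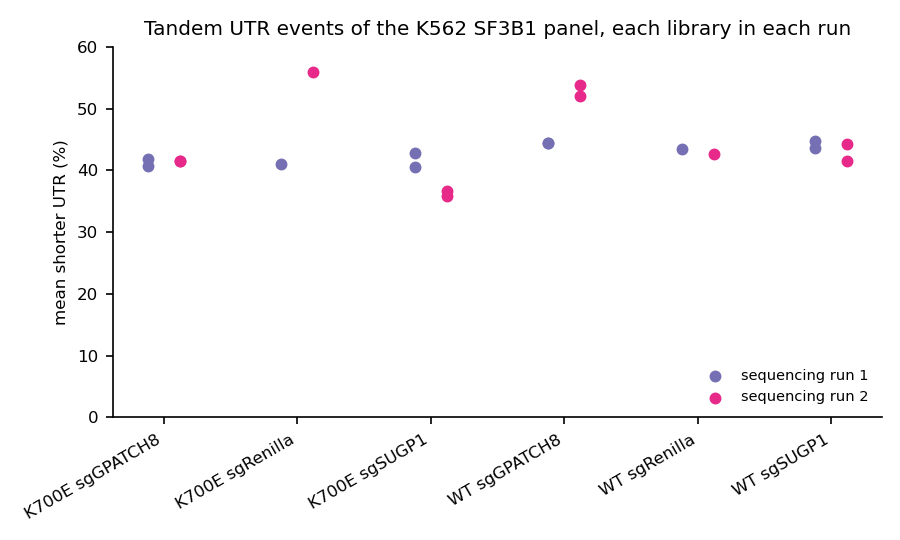
Mean usage in percent of the shorter 3' UTR over tandem 3' UTR events (vertical axis) in each column of the SF3B1 panel, by library and sequencing run. The columns span 40.6% to 44.7% in run 1 and 35.9% to 56% in run 2.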

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

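The tests of the sequencing runs, of the P95H calls and of the libraries numbered 1 were chosen after those results were seen. The counts over other splits of the samples were planned.

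A difference between groups, tested as an interaction, marked 15 events in the SF3B1 panel, where the effect of sgGPATCH8 differed between K700E and WT. DNAJC2 differed by 30.2 points. The largest of the other 14, tandem 3' UTR events without a gene name, differed by −62.5, −60, −60, −50.7 and −49 points, on chromosomes 5, X, 3, 2 and 20.

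A difference between groups, tested in the same way, marked 27 events in the SRSF2 panel, where the effect of sgGPATCH8 differed between P95H and WT. The largest were PSPH (54.3 points), COL7A1 (53.7), LINC00630 (44), TRAK2 (34.7) and PRR13 (32.7), and on the other side a tandem 3' UTR event on chromosome 14 (−45.7), RABL2A (−43.7), DLEU1 (−38), SPTB (−35.7) and DNHD1 (−33.3). KRT8, from a fixed list, differed by −17.7 points.

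The calls for sgSUGP1 in K700E and for the interaction of K700E and sgGPATCH8 numbered 63, with DNAJC2, OGG1 and KRT10 among them. An event called in both would count for each. Both comparisons use the same K700E sgRenilla library, so they are not independent. The 63 calls had a median difference of 0.5 points in run 1 and 57 in run 2. Only 34 of the 63 kept their direction in run 1, which argues against an effect of losing SUGP1 or GPATCH8 that is present in both runs. Whether the runs are repeats of 1 library is not settled, so an effect in the run 2 material alone is not excluded. A swap of the sgRenilla columns in run 2 is excluded too, as their K700E difference on the called events of the SF3B1 list was 24 points in run 1 and 24 in run 2. A difference between sequencing runs stays open too: all 20 columns were nearest to a column of their own run, and tandem 3' UTR usage ranged over 4.1 points in run 1 and 20.1 in run 2. What the runs differ in is not given.

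The calls for sgGPATCH8 were 2128 with P95H and 216 with WT SRSF2. On the 29 events called for sgGPATCH8 in 293T the median was 26 points with P95H and 25 with WT. It was 26.2 and 24 on 14 events called in WT U2AF1 cells, and 29.3 and 26 on 15 called in S34F U2AF1 cells. A much larger effect with P95H was thus not seen on such events. No interval was computed, so a somewhat larger effect is not excluded. A larger effect on events that sgGPATCH8 moves the same way in WT stays open: of the calls made with P95H and not with WT, 76.2% went the same way in WT, against 55.4% of events of the number 1 difference not called for sgGPATCH8. A difference between libraries that also separates the U2AF1 libraries numbered 1 stays open as well: of 1892 calls made with P95H and not with WT, 90.8% went its way, against 66.7% of the WT calls. Of 1709 such calls 64.1% went the way of sgGPATCH8 in 293T, against 52.8% of the number 1 events not called for sgGPATCH8. Leaving out events called for sgGPATCH8 in either SRSF2 genotype can itself lower the shares of 55.4% and 52.8%. The gaps to 76.2% and 64.1% therefore cannot separate an effect of sgGPATCH8 from the number 1 difference. Comparisons that do not test GPATCH8 loss also lay far from an even split. Of 2032 P95H calls 694 had the sign of averaged K700E and 736 that of SUGP1 loss in WT cells. Changes unrelated to GPATCH8 are therefore not excluded as the whole cause. The shares of 67.3% in WT and 80.9% in S34F U2AF1 cells come from the panel with the number 1 difference and are not independent of it. Whether the shared difference lies in the cells or in the libraries stays open, and no test here separates these.

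All 12 libraries of the U2AF1 panel correlated best with one of their own number. This restates that the libraries numbered 1 lie apart, so a difference between library batches and one between cell stocks or cultures cannot be told apart. The difference between number 1 and the others reached 4921 events, 2239 up and 2682 down, with PSPH, TRAK2 and KRT8 among them. No biological explanation was tested, since no group of the design follows the number.

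Other splits of the libraries were counted. For K700E averaged over the guide targets, 1 of 36 splits, the real one with 1713 calls, gave as many, and the highest other gave 49. That is a share under 0.05 and the smallest that 36 splits can give, so chance is unlikely but not excluded. For the interaction of P95H and sgGPATCH8, 1 of 100 shuffles gave as many as the real 27 and the highest other gave 4, so chance is unlikely. Shuffling single libraries does not address the difference shared with the U2AF1 libraries numbered 1. The interaction of S34F and sgGPATCH8 had 0 calls by limma and 1910 events at an unadjusted p under 0.05, where 2171 are expected with no change. For it 100 of 100 shuffles gave as many calls, the highest 4, which decides nothing, since no count lies below 0.

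With 3 libraries against 3 the 10 splits are too few for a share under 0.05, and in each case 1 of 10, the real one, gave as many. In the SRSF2 panel the real split gave 475 calls for P95H (highest other 0), 216 for sgGPATCH8 with WT (highest other 1) and 2128 with P95H (highest other 1). In the U2AF1 panel the real split gave 15 calls for sgGPATCH8 with S34F (highest other 1). Where the numbers pair the libraries, it gave 1 for S34F and 14 for sgGPATCH8 with WT. The 3 other splits that part all pairs gave at most 0 in each, and the 6 that keep a pair together gave at most 0 and 1.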

How the results depend on the processing

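The settings that allow a missing value, leave out tandem 3' UTR events, use both runs as columns, leave out the libraries numbered 1 together, take a guide alone or use the 293T sgSUGP1 events were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out libraries or runs leaves fewer values.

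With an offset of 0.05 the calls in the SF3B1 panel were 22 for K700E in sgRenilla, 30 for sgGPATCH8 in K700E, 73 for sgSUGP1 in K700E and 39 for the interaction of K700E and sgGPATCH8. They were 55 for the interaction in the SRSF2 panel and 39 for sgSUGP1 in 293T. A minimum of 10 points left 1413 calls for sgGPATCH8 with P95H, and no other count moved by over 1.5 times. With a missing value allowed, sgSUGP1 gave 0 calls in WT and 29 in K700E, the SRSF2 interaction 15, and 293T 15 for sgGPATCH8 and 11 for sgSUGP1.

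With the replicate number as a block, limma called 706 events for averaged K700E and 0 for sgGPATCH8 in WT, 0 for sgGPATCH8 in K700E, 0 for sgSUGP1 in WT, 0 for sgSUGP1 in K700E and 0 for the interaction of K700E and sgGPATCH8. In the SRSF2 panel the block gave 87 for P95H, 120 for sgGPATCH8 with WT and 5 for the interaction. Where the numbers pair the U2AF1 libraries, the block gave 15 for S34F and 25 for sgGPATCH8 with WT. It gave 32 for sgGPATCH8 with S34F, where the pairs correlated at 0.27, 0.09 and 0.09 and were not taken as pairs. In 293T it gave 0 and 0.

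In sequencing run 1 only, averaged K700E had 117 calls, and sgGPATCH8 and sgSUGP1, each in WT and in K700E, and the interaction of K700E and sgGPATCH8 had 0 each. In sequencing run 2 only, the counts were 21 for K700E in sgRenilla, 277 averaged, 6 and 36 for sgGPATCH8 in WT and K700E, 0 and 1121 for sgSUGP1, 310 for the interaction with sgGPATCH8 and 53 with sgSUGP1. Both runs as columns gave 844, 3907, 286 and 355 for sgGPATCH8, 358 and 31 for sgSUGP1, and 7 and 50 for the interactions, with a correlation between runs of a library of −0.147, so these counts are liberal. Without tandem 3' UTR events, sgGPATCH8 in K700E had 2 calls, sgSUGP1 in K700E 4 and the interaction with sgGPATCH8 0. HMG20B, SIRT7 and RAP1B turned direction in run 1, at 0.5, 3 and 5 points against −44, −36.8 and −36 over both runs.

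With a library left out, averaged K700E had 213 to 474 calls: 474 and 425 without WT sgGPATCH8 replicate 1 or 2, 388 and 340 without WT sgSUGP1, 386 and 269 without K700E sgGPATCH8, and 213 and 250 without K700E sgSUGP1. The other SF3B1 comparisons of sgGPATCH8, sgSUGP1 and their interactions had 0 to 0, as did sgGPATCH8 and sgSUGP1 in 293T without any of their 6 libraries. For K700E in sgRenilla no library was left out. A group left with 1 library is assumed to vary like the others. In the SRSF2 panel every library moved the counts by over 1.5 times, to 79 to 111 for P95H, 104 to 120 for sgGPATCH8 with WT, 1107 to 1310 with P95H and 5 to 12 for the interaction. For U2AF1, S34F had 0 to 1, with 0 without WT sgRenilla replicate 1 or 2 or S34F sgRenilla replicate 1, 2 or 3, and CTNNB1 lost its call without any of the 6. There, sgGPATCH8 with WT had 5 to 12 (5, 8, 6 and 5 without WT sgRenilla replicate 2 or 3 or WT sgGPATCH8 replicate 2 or 3) and with S34F 4 to 17 (5, 4, 9 and 4 without S34F sgRenilla replicate 2 or 3 or S34F sgGPATCH8 replicate 1 or 3). The interaction had 0 to 1, with 1 without S34F sgGPATCH8 replicate 1. Without the 4 libraries numbered 1 the U2AF1 counts were 0 for S34F, 0 for sgGPATCH8 with WT and 0 with S34F.

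In 293T guide 16 alone gave 0 calls and guide 17 alone 14 for sgGPATCH8, and guide 3 alone 2 and guide 4 alone 8 for sgSUGP1. The difference in K700E effect with and without GPATCH8, 2.5 points, was −1.2 on the events of the fixed SF3B1 list, −1.7 on the events called for averaged K700E and −3 on those called for sgSUGP1 in 293T. The correlation of sgSUGP1 effects between cell lines was 0.121 with an offset of 0.1, against 0.128. The lists of SF3B1, SRSF2 and U2AF1 targets kept 20, 3 and 0 called genes with a minimum of 10 points.

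Of the values of named events under these settings, 581 of 1050 in the SF3B1 panel kept direction and call, 925 of 1476 in the SRSF2 panel, 148 of 264 in the U2AF1 panel and 100 of 396 in 293T. The rest lost the call, and 3 of them, given above, turned direction. A difference of 0 was counted as kept direction, and an event not tested under a setting gave no value. The 3 are therefore a lower limit: DNAJC2, called for the interaction of K700E and sgGPATCH8, lay 1.5 points in the other direction in run 1. Not run were all settings of gene levels and of gene lists by level, the SRSF2 panel with run 1 only, the WT-1 groups of 293T alone, and the K700E effect in run 1, where no event was picked in the sgSUGP1 libraries (0 calls by limma, 4394 events at an unadjusted p under 0.05). Depth is unknown, so what it limits could not be examined.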

Other observations

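Among the genes named from the fixed lists, SNHG1 and GAS5, noncoding hosts of small nucleolar RNAs, spliced an intron less without GPATCH8 in P95H SRSF2 cells. SNHG1 fell from 37.3% ± 4.6 (SD, n = 3) to 4% ± 1.7 (n = 3; limma adjusted p 0.0022) and GAS5 from 82% ± 1 to 60.3% ± 1.5. Their list, nonsense-mediated decay factors and targets, did not pass the test against other genes there (4 of 15, two-sided Fisher's exact p 0.15, Benjamini-Hochberg adjusted 0.32), and 180 of 239 called retained introns fell. Inclusion of an exon of the proliferation marker MKI67 fell from 53% ± 1.7 to 28.7% ± 0.6 in the same cells, and intron splicing in the stress gene DDIT3 fell from 68.3% to 55%. As with the other P95H calls, these values lie in the group that shares a difference with the U2AF1 libraries numbered 1.

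PSPH in the U2AF1 panel used the shorter intron in 87% to 96% of transcripts in the 4 libraries numbered 1 and, among the other 8 libraries, in 54% to 71% with sgGPATCH8 and in 28% to 44% with sgRenilla. The 10 libraries of the SF3B1 panel had 90% to 97%.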
